A study of Mus musculus with 6 samples.

How the data were processed

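Total RNA from the left ventricle of 6 obese male mice was hybridised to Affymetrix mouse expression arrays, 1 array per mouse, as biotin-labelled target. The sample description names left ventricle as the RNA source, while the extraction text in the labels speaks of blood. The ventricle is taken as the source because the design text gives it too and because heart transcripts such as Myh6 were among the brightest signals. The deposited values are linear signal intensities, 1 per probe set and array, that the authors made with Affymetrix Expression Console, per the submitters' processing notes. The version and the summarisation algorithm are not given in the sources used here. The deposited intensities have a 2% trimmed mean of 150 on each array and are neither log transformed nor quantile normalised, as checked on the values. No detection calls were used here, so a dim signal could not be told from background, and low values were filtered by their mean. Scaling each array to one trimmed mean removes differences in total signal, so that only changes relative to the other genes can be seen. No genome build is named in the sources used here and no coordinates are given.

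Samples were grouped by the agent in the labels, with 3 placebo and 3 Lira mice. The 64 control probe sets were left out. Of 45101 probe sets, 35890 were in the name table used, 34958 of them with 1 gene and 932 with several, and 9211 were not in it. Names were updated through gene IDs to RefSeq symbols of the mouse assembly GRCm38.p6, and 99.42% of the single-gene probe sets matched (34754). Probe sets with several genes were not named or tested. Each of 18194 genes was represented by the probe set with the highest mean over all 6 arrays. Values were taken as log2(signal + 16), and the 30% of genes with the lowest mean were left out, which leaves 12736 genes with a mean signal of at least 21.9. Fold changes are on this scale, which understates the change of dim genes. Lira was compared with placebo in limma 3.58.1 under R 4.3.3, with lmFit, eBayes with a variance trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. A looser count took an unadjusted p under 0.05 and a change of at least 1.5-fold.

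Before the data were examined, 33 pathway lists and 22 cell type marker lists were fixed, 55 in all, with the tests, the alternatives and the rule for named genes. The 47 lists with at least 4 tested members were tested with camera at its preset inter-gene correlation of 0.01, and their p-values were adjusted over these lists. Some genes stand on more than one list. An adjustment over a list alone does not correct for the number of lists looked at, so passing it is weak support. Members without a tested probe set were not analysed here. The rule names up to 12 genes in each direction past the adjusted threshold whose groups do not overlap, filled up with the largest changes at an unadjusted p under 0.01 whose groups do not overlap, without uncharacterised transcripts. It also names the 4 members with the smallest p of each passing list, up to 2 of any other list described, members past the threshold adjusted over the list alone, and a fixed set of heart and metabolic genes. Genes named beyond the rule, which are 2210407C18Rik, Cryab, Dusp1, Eif2s3y, Depp1, Gadd45a, Fbxo32, Trim63, Sesn1, Ptprc, Dbp, Arntl, Myl7, Myl4, Sln, Bmp10, Myh2 and Tnni2, were chosen after the values had been seen or as members of a tested set.

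The fit was tested on 10 simulated data sets of 3 against 3 arrays for this comparison, made from the real means of the 12736 genes with 200 genes changed. Their spreads were drawn from the variance trend that limma had fitted to the real arrays. The simulation therefore could not test whether that trend holds. The fit called 64.8% of genes changed 2-fold and 27.2% of genes changed 1.5-fold, and 4.4% of calls were false. A list shifted by 0.25 was called in 10 of 10 data sets and 0 unshifted lists were called. Simulated genes varied independently of each other, unlike genes in tissue, so these list results are a best case. Alternatives tried were quantile normalisation, median centring, other filters and pseudocounts, the mean of a gene's probe sets, no variance trend, a robust prior, array weights, a block for the replicate number, every probe set in place of genes, other thresholds, camera with an estimated correlation, fry, and each array left out in turn.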

Results

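Gene expression was measured in the left ventricle of 6 male C57BL/6 mice, an inbred strain that becomes obese on fat-rich food. The mice were 6 months old and had eaten a high fat diet for 16 weeks. 3 mice received placebo and 3 received an agent that the labels call Lira, which they do not spell out, so the name is kept as given. The design text speaks of 10 mice, and mice beyond these 6 were not analysed here. Each mouse gave 1 array with 45101 probe sets, which report transcript abundance as a fluorescence signal in arbitrary linear units. The 2% trimmed mean signal was 150 on every array, and the median signal per array lay between 28.6 and 39.6. Array data carry no read depth, and the number of arrays limits the precision of every value. The Y-linked transcript Eif2s3y gave signals of 465.2 to 826.5 on its brighter probe set, and no Xist probe set exceeded 80.2 on any array. The labels give the sex as male.

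The comparison addressed by the design is the effect of Lira on the heart of obese mice. The transferrin receptor Tfrc, which carries iron into cells, fell with Lira from 1355 ± 54.2 to 656 ± 87.1 signal units (SD, n = 3 per group), a 2.05-fold decrease. Ddit4, an inhibitor of mTORC1 signalling that stress induces, fell from 2052 ± 273 to 1227 ± 53.7. Acta1, the skeletal alpha-actin that the fetal and the overloaded heart express, fell from 2975 ± 506 to 1590 ± 263. Rgcc, a regulator of the cell cycle, fell from 3255 ± 889 to 1446 ± 273. Rrad, a small GTPase that restrains L-type calcium channels, rose from 736 ± 185 to 1446 ± 149. Ano10, of the anoctamin family of membrane proteins, rose from 817 ± 81.3 to 1592 ± 238, and the uncharacterised transcript 2210407C18Rik rose from 142 ± 29.7 to 325 ± 26.4.

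These 7 genes, 3 higher and 4 lower, were the genes past an adjusted p of 0.05 among 12736 genes tested with limma and Benjamini-Hochberg adjustment, and in each of them all 3 Lira arrays lay on one side of all 3 placebo arrays. The log2 changes, Lira minus placebo, were -1.03 ± 0.11 (SE) for Tfrc with an adjusted p of 0.0029, 0.94 ± 0.12 for Ano10 (adjusted p = 0.014) and 1.12 ± 0.15 for 2210407C18Rik (adjusted p = 0.017). They were -0.73 ± 0.10 for Ddit4, -1.15 ± 0.17 for Rgcc and -0.90 ± 0.13 for Acta1, each with an adjusted p of 0.023, and 0.99 ± 0.16 for Rrad (adjusted p = 0.042). 2210407C18Rik fell outside the rule for named genes and was added after its values were seen. The Entrez gene IDs are 22042 for Tfrc, 102566 for Ano10, 78354 for 2210407C18Rik, 74747 for Ddit4, 66214 for Rgcc, 11459 for Acta1 and 56437 for Rrad. Acta1 has near-identical actin relatives whose transcripts its probes may not tell apart. Tfrc has 2 further probe sets that are dim, at 35.5 and 17.4 signal units with placebo, and they gave log2 changes of -0.14 and -0.02. With the mean of each gene's probe sets in place of the brightest, the log2 change of Tfrc was -0.40 and no gene passed, and without the variance trend no gene passed either, with 684 and 691 genes at an unadjusted p under 0.05 in limma. Tfrc passed with each array left out in turn. Without Lira replicate 3 no other gene passed, with adjusted p from 0.13 for Ano10 to 0.39 for Rrad. Without placebo replicate 2 the other 6 genes missed the threshold at 0.058 to 0.068. Without Lira replicate 2 Ano10 (0.057), Ddit4 (0.073), Rgcc, Rrad and 2210407C18Rik (0.067 each) missed it, without Lira replicate 1 Ddit4 (0.071), 2210407C18Rik (0.076), Acta1 (0.13) and Rrad (0.18), and without placebo replicate 1 Ddit4 (0.075) and Rrad (0.081). The number of genes that passed was 1 without Lira replicate 3, 2 without placebo replicate 2, 3 without Lira replicate 2 and 4 without Lira replicate 1.

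**Figure D1:**
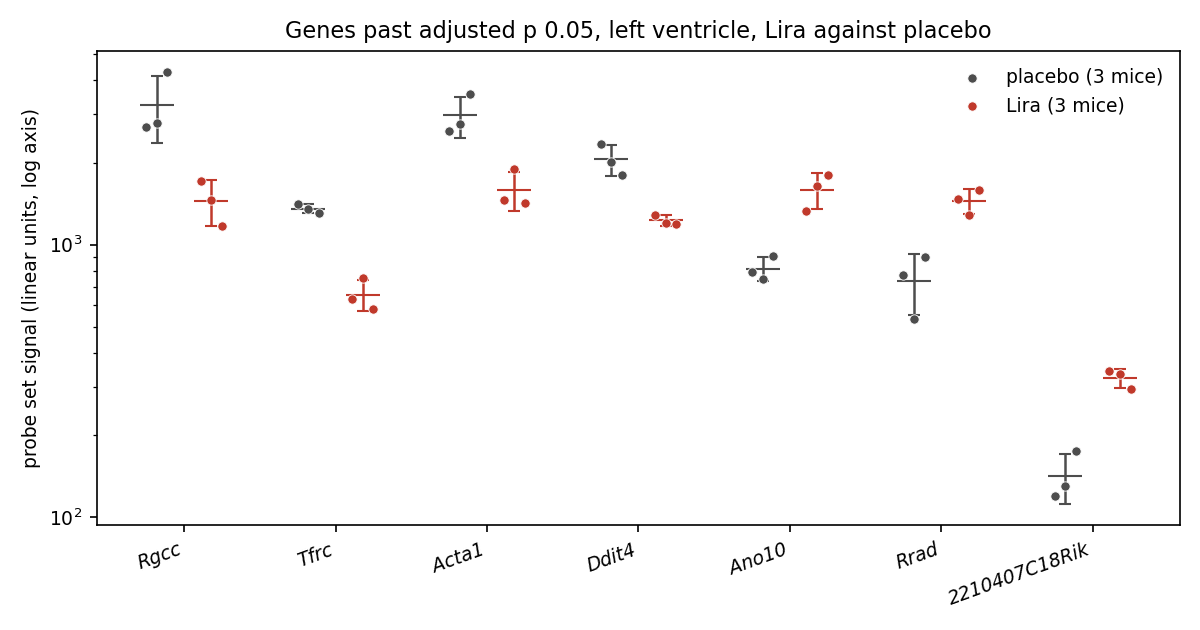
Probe set signal (linear units, log axis) of the 7 genes past adjusted p 0.05 in placebo (grey) and Lira (red) left ventricles. Points are single mice, horizontal bars are group means and error bars are SD (n = 3). The 3 Lira mice lie below all placebo mice for Rgcc, Tfrc, Acta1 and Ddit4 and above them for Ano10, Rrad and 2210407C18Rik.

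At a looser threshold, an unadjusted p under 0.05 with a change of at least 1.5-fold, 146 genes were counted, 58 higher and 88 lower with Lira. Of 10 splits of the 6 arrays into 3 and 3, 7 reached 146 genes, the real one among them. The highest other split gave 338, so the 146 do not exceed what groupings other than treatment give. At an unadjusted p under 0.05 alone there were 765 genes, where chance gives 637 if the p-values are calibrated. The 146 became 267 without Lira replicate 2 and 233 without Lira replicate 3. The balance of directions was not stable, with 139 higher and 94 lower without Lira replicate 3, 105 and 89 without placebo replicate 2, 89 and 88 without placebo replicate 3, and 67 and 200 without Lira replicate 2. The groups did not overlap in 1461 genes, or 11.5% of those tested, where chance gives 10%. Of the genes the rule names without an adjusted p under 0.05, those with the largest higher values were Ccl12, a monocyte-attracting chemokine, at 14.2 ± 10.8 with placebo and 84.8 ± 37.6 with Lira (adjusted p = 0.26, and 0.0076 to 0.89 in the alternatives), then Opn3, Cnmd, Gfod2, Amer1, Lce3b, Scarf2, Fbxl15, Ahr and Acta2. Ccl12 shares much of its sequence with other chemokine genes, and 1 of the 2 probe sets of Amer1 and 1 of the 3 of Scarf2 had the other sign. Opn3, Cnmd, Gfod2, Amer1, Lce3b and Fbxl15 were dim, with placebo means from 18.1 for Cnmd to 42.3 for Fbxl15. The groups of Opn3 were barely apart, at 43.4 on Lira replicate 1 and 43.1 on placebo replicate 1. Ahr, the aryl hydrocarbon receptor, measured 94.6 ± 22.4 and 183 ± 10.7 (adjusted p = 0.16). Acta2, the smooth muscle actin, measured 1196 ± 170 and 2158 ± 1056, with 3377 in Lira replicate 1 and at most 1579 on any other array, and passed adjusted over the smooth muscle markers alone. The lower ones were Hspa1b, Trim69, Irs2, Cyp46a1, Hspa1a, Bad, Kcnmb4 and Acsf2. Trim69, Cyp46a1 and Kcnmb4 were dim, with Lira means of 9.02, 11.5 and 16.6. The insulin receptor substrate Irs2 measured 110 ± 45.2 with placebo and 37.4 ± 23.3 with Lira, a log2 difference of -1.30 ± 0.34, and its relative Irs1 measured 443 ± 56.5 and 674 ± 150, a difference of 0.57 ± 0.15. Adjusted over the list alone, both passed within the insulin signalling genes, and over all genes neither did (adjusted p of 0.51 for Irs2 and 0.53 for Irs1).

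Of 47 gene lists tested for a shared shift against all other genes, 7 passed an adjusted p of 0.05 in camera with its preset correlation of 0.01, 4 lower and 3 higher with Lira. With the correlation estimated for each list, 0 of the 7 passed, and fry gave 0 as well. At an unadjusted p under 0.05 both also gave 0. The 7 lists became 3 without placebo replicate 1 and 4 without Lira replicate 2. The genes within a list varied together between mice, with estimated correlations from 0.136 to 0.502 in these 7 lists, all above the preset of 0.01. Log2 differences of the list means, with SE from the arrays, were -0.26 ± 0.10 for heat shock, -0.18 ± 0.11 for glucocorticoid targets and -0.16 ± 0.11 for immediate early genes. They were -0.10 ± 0.09 for extracellular matrix, 0.22 ± 0.14 for antigen presentation, 0.16 ± 0.10 for macrophage markers and 0.14 ± 0.11 for interferon response. Only the heat shock mean lay beyond 2 SE of 0.

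Heat shock genes, the chaperones that protect proteins under stress, were shifted lower with Lira at the preset correlation in camera. Of 19 tested members 15 were lower and 4 higher, with a median log2 difference of -0.09 and a mean of -0.26 (adjusted p = 6.1e-05, camera; adjusted p = 0.70 with an estimated correlation). 0 members passed over all genes, and 5 passed adjusted over the list alone, all lower: Hspa1b, Hspa1a, Hspb6, Dnaja1 and Hsp90aa1, which had the same sign on 3 of its 5 probe sets. Hspa1b, an inducible Hsp70 gene, measured 839 ± 309 with placebo and 270 ± 136 with Lira, a log2 difference of -1.60 ± 0.29. Its near-identical neighbour Hspa1a, whose transcripts the probes may not tell apart, measured 266 ± 98.6 and 110 ± 40.7. Over all genes Hspa1b passed with median centring (8.4e-04), without placebo replicate 2 (0.036) and without Lira replicate 2 (0.0084), and Hspa1a with median centring (0.043), with values up to 0.89 for both without the variance trend. Hspb6, a small heat shock protein abundant in heart, measured 18896 ± 416 and 15365 ± 889, and the co-chaperone Dnaja1 1934 ± 279 and 1376 ± 215. Cryab, another abundant small heat shock protein, differed by 0.002 ± 0.08. The list mean was lower in all 3 Lira arrays than in any placebo array, a separation that chance gives in 10% of cases. The nearest arrays were placebo replicate 2 at -0.021 and Lira replicate 2 at -0.060. Means of the lymphatic endothelial and apoptosis lists were also lower in all Lira arrays. Those of the cAMP signalling list and the T cell and NK cell markers were higher in all. In camera at the preset correlation the heat shock list passed with each array left out in turn, at 1.2e-07 to 0.0038. Without Hspa1a and Hspa1b it still had an adjusted p of 0.0047.

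Targets of the glucocorticoid receptor and immediate early genes, which hormones and nerve activity induce within minutes to hours, were also shifted lower at the preset correlation. Of 15 tested glucocorticoid targets 12 were lower and 3 higher, with a median log2 difference of -0.23 (adjusted p = 9.2e-04, camera; adjusted p = 0.70 with an estimated correlation). Ddit4 passed over all genes and was also the one member past the threshold adjusted over the list alone. The kinase Sgk1 measured 1670 ± 59.3 and 1339 ± 170, the clock gene Per1 446 ± 126 and 307 ± 61.4, and the receptor co-chaperone Fkbp5 369 ± 42.2 and 282 ± 69.0. Dusp1, a further target, differed by -0.01 ± 0.13. Of the 15 targets 9 stand on other lists too, with Per1 and Dusp1 also among the immediate early genes, so the shifts of these lists are not independent of each other. Of 24 immediate early and cAMP-response genes 19 were lower and 5 higher, with a median of -0.13 (adjusted p = 0.014, camera; adjusted p = 0.70 with an estimated correlation). 0 of them passed over all genes and Klf4 passed adjusted over the list alone, at 1150 ± 111 and 842 ± 7.06. The nuclear receptor Nr4a1 measured 892 ± 497 and 438 ± 140, and the salt-inducible kinase Sik1 148 ± 41.1 and 95.1 ± 14.9, with the other sign on 1 of its 2 probe sets. Without Lira replicate 2 the adjusted p was 0.21 for the glucocorticoid targets and 0.18 for the immediate early genes, and without placebo replicate 1 it was 0.33 for the immediate early genes, which also missed the threshold without the variance trend (0.070) and with array weights (0.076). Leaving out single arrays gave 1.6e-05 to 0.21 for the glucocorticoid targets and 1.4e-04 to 0.33 for the immediate early genes.

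Antigen presentation genes, macrophage markers and interferon response genes were shifted higher with Lira at the preset correlation in camera. Of 14 tested antigen presentation genes 13 were higher and 1 lower, with a median log2 difference of 0.26 (adjusted p = 2.2e-04, camera; adjusted p = 0.70 with an estimated correlation). The peptide transporter Tap2 measured 139 ± 21.5 with placebo and 188 ± 10.8 with Lira, the class II gene H2-Aa 1203 ± 86.1 and 1498 ± 277, and the class I gene H2-D1 2398 ± 260 and 2853 ± 249, with the same sign on 7 of its 9 probe sets. The class II chaperone Cd74 measured 404 ± 13.3 and 516 ± 120. Of 18 macrophage markers 15 were higher and 3 lower, with a median of 0.16 (adjusted p = 0.0053, camera; adjusted p = 0.70 with an estimated correlation). Among them were the lysozyme Lyz1, at 1721 ± 196 and 2197 ± 314, the complement gene C1qc, at 384 ± 24.5 and 468 ± 12.7, and Mpeg1, at 150 ± 6.48 and 211 ± 52.9. Gpnmb was dim, at 32.2 ± 22.6 and 55.1 ± 2.67, with overlapping groups and the other sign on 1 of its 2 probe sets. Of 19 interferon response genes 12 were higher and 7 lower, with a median of 0.11 (adjusted p = 0.026, camera; adjusted p = 0.70 with an estimated correlation). 0 genes of the 3 lists passed over all genes. Adjusted over the list alone, 1 interferon response gene passed, the immunity-related GTPase Iigp1 at 748 ± 102 and 1106 ± 147, and 0 genes of the other lists. Further interferon response genes were Igtp, at 368 ± 62.8 and 582 ± 177 with overlapping groups, and Rsad2, at 412 ± 56.7 and 517 ± 50.5. Psmb8, also on the antigen presentation list, measured 190 ± 12.9 and 237 ± 31.3. A set of 13 general leukocyte genes, among them Ptprc, had a mean 0.20 ± 0.07 (SE) higher with Lira on the log2 scale. Without the genes it shares with antigen presentation, the interferon response list had an adjusted p of 0.098. Lyz1 was higher by 0.345 on the probe set used, but its other probe sets did not show this rise. They measured 715 with placebo and 615 with Lira (log2 difference -0.13), and 8.20 and 8.67 (0.01). Antigen presentation had an adjusted p of 0.18 without Lira replicate 2. Macrophage markers had 0.17 without placebo replicate 1 and 0.16 without Lira replicate 1, and the interferon response had 0.32 without placebo replicate 1 and 0.35 without Lira replicate 2, as well as 0.070 without the variance trend and 0.10 with array weights.

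Extracellular matrix genes were shifted lower with Lira at the preset correlation in camera. Of 28 tested members 19 were lower and 9 higher, with a median log2 difference of -0.15 (adjusted p = 0.014, camera; adjusted p = 0.70 with an estimated correlation). 0 members passed over all genes and 3 passed adjusted over the list alone, all lower. They were the matricellular protein Sparc, at 1977 ± 215 with placebo and 1450 ± 55.9 with Lira, the collagen gene Col3a1, at 1597 ± 99.9 and 1135 ± 255, and Col8a1, at 240 ± 28.4 and 169 ± 18.8. Postn, which did not pass, measured 424 ± 54.3 and 325 ± 22.1. Col1a1 differed by -0.02 ± 0.24 on the probe set used and by -0.53 on its other one. The list had an adjusted p of 0.22 without placebo replicate 1, 0.22 without Lira replicate 2 and 0.25 without Lira replicate 3, and it also missed the threshold with median centring (0.057), array weights (0.065) and the mean of each gene's probe sets (0.13).

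**Figure D2:**
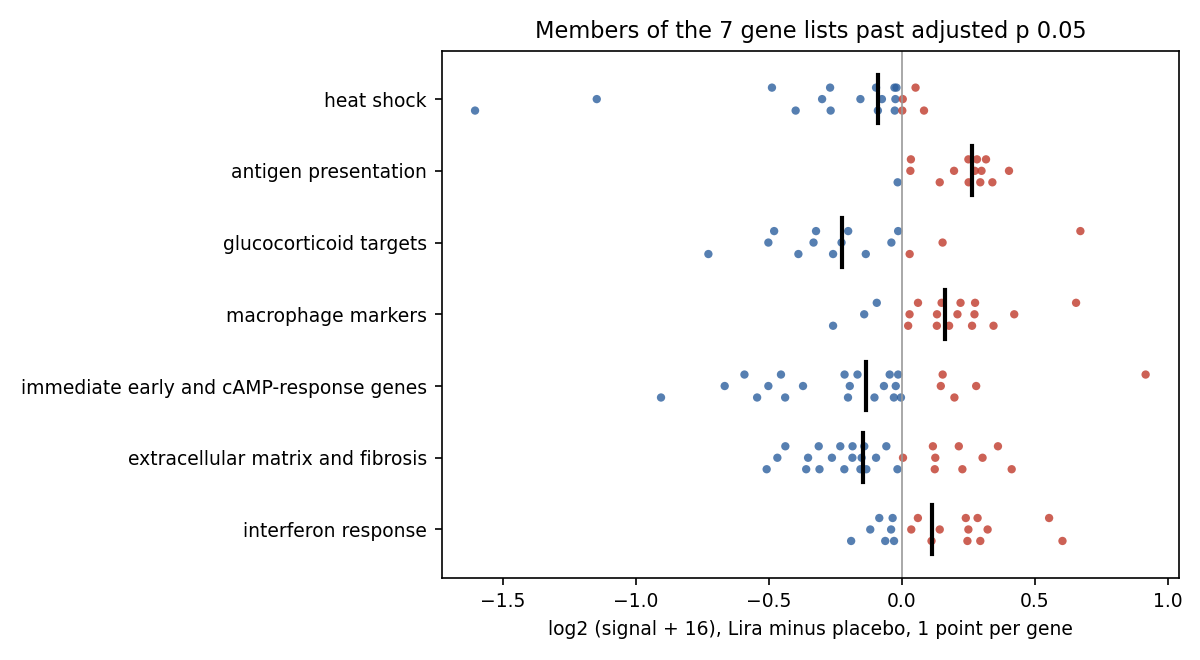
Difference in log2(signal + 16), Lira minus placebo, of each tested gene (1 point per gene, red above 0 and blue below) in the 7 lists past adjusted p 0.05 in camera. Black bars mark the list medians, from -0.23 for glucocorticoid targets to 0.26 for antigen presentation, and the 2 genes farthest to the left are Hspa1b and Hspa1a.

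**Figure D3:**
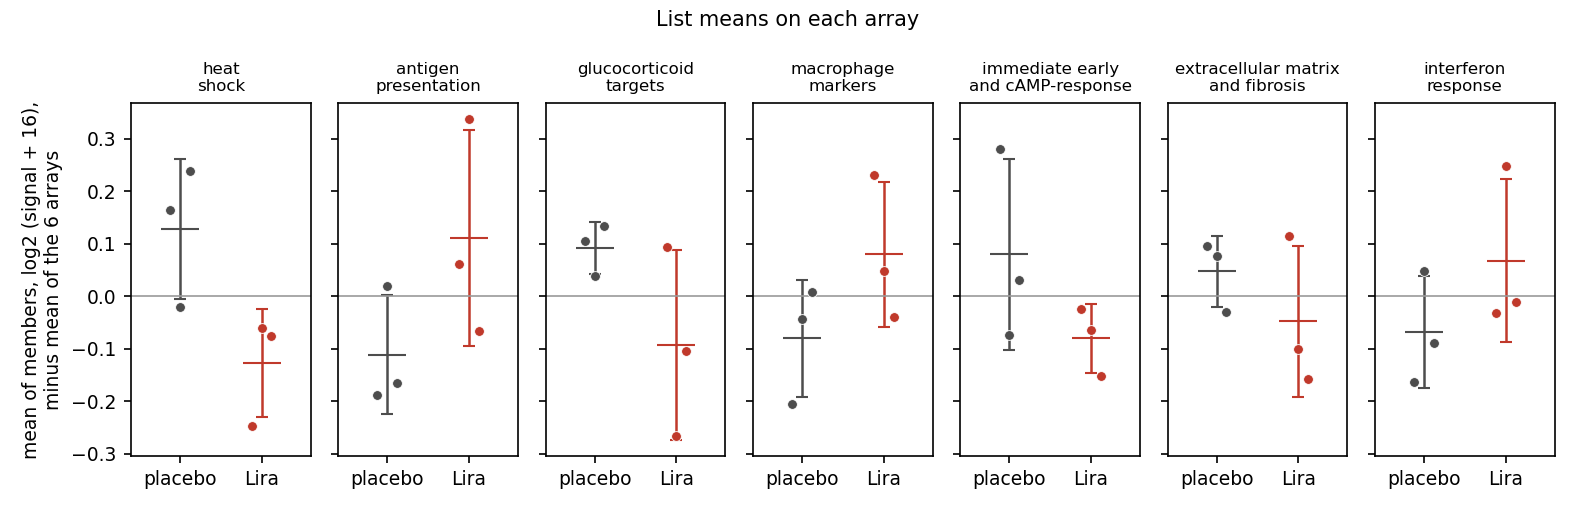
Mean of each list's members on each array, as log2(signal + 16) minus the mean of the 6 arrays, for the same 7 lists. Points are single mice, horizontal bars are group means and error bars are SD (n = 3). The 3 Lira mice lie below all 3 placebo mice for heat shock, which chance gives in 10% of cases, and the groups overlap for each of the other 6 lists.

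Genes of cardiac stress and hypertrophy gave single genes with lower values and no list shift. Of 15 tested fetal and hypertrophy genes 8 were higher and 7 lower, the median was 0.02 and the mean -0.09, and the list did not pass (adjusted p = 0.33, camera). Acta1 passed over all genes. Adjusted over the list alone, which does not correct for the number of lists, 4 genes passed, all lower with Lira: Acta1, Nppa, Myh7 and Ankrd1. Nppa, which encodes atrial natriuretic peptide, measured 2831 ± 214 with placebo and 1797 ± 382 with Lira, a log2 difference of -0.67 ± 0.13 (adjusted p = 0.17 over all genes). The slow myosin Myh7 measured 1610 ± 408 and 1041 ± 62.3 (adjusted p = 0.44), and Ankrd1, a stretch-responsive nuclear protein, 9393 ± 1484 and 6972 ± 873. Nppb, the gene of brain natriuretic peptide, measured 3696 ± 1530 and 2671 ± 194, a difference of -0.37 ± 0.24 (adjusted p = 0.87). Without placebo replicate 1 the difference was -0.77 for Nppb and -0.79 for Myh7, and both passed over all genes (adjusted p = 0.040 each), the lowest of their alternatives, which reached 0.999 for Nppb and 0.89 for Myh7. The adult myosin Myh6 differed by 0.11 ± 0.09 and by 0 after quantile normalisation, where it is the brightest gene on each array, and the calcium pump Atp2a2 by 0.15 ± 0.10, with values from 0.15 to 0.50 on its 6 probe sets. Of 7 tested atrial markers 5 were higher and 2 lower (adjusted p = 0.88, camera), Nppa among the lower. All 6 tested skeletal muscle markers had lower values, with a median of -0.33 (adjusted p = 0.061, camera; 0.70 with an estimated correlation), and the list passed with median centring (0.015), without the variance trend (0.041), without placebo replicate 2 (0.025) and without Lira replicate 2 (0.015), with leave-one-out values up to 0.32.

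Energy metabolism genes gave no list past the threshold with all 6 arrays. Of 14 PPAR target genes 9 were lower and 5 higher, with a median log2 difference of -0.16 (adjusted p = 0.15, camera; adjusted p = 0.70 with an estimated correlation). This list passed without Lira replicate 1 (6.2e-04) and without placebo replicate 3 (0.041), and had 0.73 without Lira replicate 3. The median difference was 0.01 over 22 genes of fatty acid uptake and oxidation, 0.04 over 18 genes of glucose uptake and glycolysis, 0.01 over 17 genes of the TCA cycle and 0.01 over 45 genes of oxidative phosphorylation, with adjusted p of 0.88, 0.88, 0.91 and 0.62 in camera. The test direction was down for fatty acid oxidation, against a median and a mean above 0. The kinase Pdk4, which shuts glucose out of mitochondria, differed by -0.26 ± 0.25, the fatty acid transporter Cd36 by 0.19 ± 0.13, with -0.07 on 1 of its 3 probe sets, and the glucose transporter Slc2a4 by 0.09 ± 0.13, with 0.56 on its other probe set. The regulators Ppara and Ppargc1a differed by -0.07 ± 0.11 and -0.05 ± 0.16, and Ucp3 by -0.04 ± 0.24, each with probe sets of both signs. The endothelial nitric oxide synthase Nos3 differed by -0.04 ± 0.14. None of these 7 genes passed adjusted over all genes, and the smallest adjusted p among them was 0.87. Cpt1b was measured only by a probe set that several genes share and was not tested. Signals of Glp1r, the receptor for the gut hormone GLP-1, lay between 1.9 and 16, and those of Tnf between 7.8 and 40.6, and both fell below the filter on low values.

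Over all genes, correlations between arrays of different groups were as high as within groups. Pearson correlations across genes, which are not independent replicates, ran from 0.9744 to 0.9804 within groups and from 0.9753 to 0.9818 between groups. The first principal component held 28.1% of the variance and the second 21.1%. Scores on the first overlapped between the groups and rose in the same order as the mean log2 signal of the spike-in control probe sets. They ran from -24.7 on Lira replicate 3 (control signal 11.901) to 22.16 on Lira replicate 2 (12.318). On the second the placebo arrays lay at 1.15, 3.17 and 25.34 and the Lira arrays at -5.85, -18.03 and -5.77, with no test of this difference. An exact permutation test of any single value between 3 and 3 mice cannot go below p = 0.1, so significance for single genes rests on the spread that limma shares across genes.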

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

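Alternatives were planned before the data were examined, except the list variants without shared or paralogous genes and the class I and class II parts of the antigen presentation list. The 7 genes past adjusted p 0.05 were 6 to 10 with quantile normalisation, median centring, the stricter filter, the robust prior, array weights, other pseudocounts or an adjusted p of 0.10. They were 1 with no filter on low values and 1 over every probe set, Tfrc each time. More features are tested in these settings, and whether this accounts for the lower counts was not tested. They were 0 with the mean of the gene's probe sets and 0 with no variance trend, where limma gave 684 and 691 genes at an unadjusted p under 0.05 and 143 and 152 at the looser threshold. Leaving out 1 array gave 1 to 9 genes. Tfrc passed in 15 of 17 settings, Ddit4 and Rrad in 8. The 146 genes at the looser threshold became 389 with no filter, 57 with the lowest 50 percent left out, 37 with pseudocount 64, 25 with fold threshold 2 and 621 over every probe set, and 177 to 267 without 1 array. The 7 lists became 4 with array weights, 0 with camera and an estimated correlation, 0 with fry, and 3 to 9 without 1 array (3 without placebo replicate 1, 4 without Lira replicate 2). The causes of these changes in number were not tested.

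Of the values whose sign turned, none had passed a test. Ucp3 became 0.038 with the mean of the gene's probe sets and 0.002 with array weights, Ppara 0.0077 with the mean of the gene's probe sets, and Ppargc1a 0.023 with array weights. Without 1 array each, values ran from -0.32 to 0.15 for Col1a1, -0.16 to 0.056 for Nos3, -0.35 to 0.26 for Ucp3, -0.0044 to 0.32 for Cd36, -0.16 to 0.13 for Ppargc1a, -0.62 to 0.0699 for Pdk4 and -0.082 to 0.25 for Slc2a4. The replicate block left 6 genes, without Rgcc (adjusted p = 0.058), 152 at the looser threshold and 7 lists. Same-numbered arrays had residual correlations of -0.034, 0.09 and -0.087, within the range of -0.152 to 0.183 for arrays with different numbers. The labels name no pairing of the mice, and so few correlations cannot exclude one. Without detection calls, the signal at which a gene stands above background is unknown.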

Other observations

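Single genes outside the heart stress, immune and matrix lists passed adjusted over their list alone without passing over all genes. That adjustment does not correct for the number of lists. The lists described here did not pass with all 6 arrays under the main processing, and some passed under the alternatives given. Gpx3, the secreted glutathione peroxidase, measured 1132 ± 88.9 with placebo and 1720 ± 149 with Lira (SD, n = 3 per group, adjusted p = 0.066, limma) and passed adjusted over the antioxidant list alone, with 0.035 to 0.89 over all genes in the alternatives. The cyclin Ccnd1 measured 785 ± 32.5 and 522 ± 51.7 and passed adjusted over the cell cycle list alone, with 0.048 to 0.89 over all genes in the alternatives. The clock gene Per2 measured 186 ± 38.0 and 104 ± 19.6 and passed adjusted over the circadian list alone, while the list of 18 clock genes, 11 lower and 7 higher, did not (adjusted p = 0.15, camera; adjusted p = 0.70 with an estimated correlation). The clock list passed with the mean of the gene's probe sets (0.0089), without Lira replicate 3 (0.012) and with the lowest 50 percent left out (0.044). Vegfa measured 1184 ± 23.8 and 896 ± 130 and passed adjusted over the hypoxia list alone, as did Ddit4, which passed over all genes too, and over the vasoactive list alone, although 1 of its 2 probe sets had the other sign. Fibroblast markers split, with Mfap5, Pi16 and Col3a1 lower and Fbln1 and Dcn higher past the threshold adjusted over the list alone, in a list of 14 whose adjusted p was 0.88. Of 20 autophagy and lysosome genes 15 had higher values, among them Gabarapl1 at 1084 ± 108 and 1514 ± 326, and the list did not pass (adjusted p = 0.061, camera; adjusted p = 0.70 with an estimated correlation). It passed with quantile normalisation (0.048) and without placebo replicate 2 (0.030), Lira replicate 1 (0.036) or Lira replicate 2 (0.015), and had 0.62 without Lira replicate 3. Of 18 cytokine and chemokine genes 14 had higher values, and the list did not pass (adjusted p = 0.15, camera; adjusted p = 0.70 with an estimated correlation) except with median centring (0.047) and without Lira replicate 3 (0.029). Of 18 ribosomal protein genes 15 had higher values (adjusted p = 0.27 in camera, and 0.82 with an estimated correlation), and the list passed without placebo replicate 3 (9.4e-04). The median and the mean differed in sign in the insulin, cell cycle, fibroblast, hypoxia, atrial, calcium handling, AMPK, muscle atrophy and conduction system lists, besides the fetal genes. The liver transcripts Alb and Ttr were highest on single placebo arrays, Alb at 130.3 on placebo replicate 2 and Ttr at 183.4 on placebo replicate 3, and were at most 40.6 on any Lira array.

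Of the tests below, those of RNA quality and both of skeletal muscle were chosen only after the result was seen. Those of signal scale and FOXO activity were each judged with a further condition that was not part of the rule written for them. For the counts, the 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. For the 7 genes past adjusted p 0.05, 1 of 10 splits, the real one, gave as many, and the highest other split gave 0. For the 146 genes at the looser threshold, 7 of 10 splits gave as many, and the highest other gave 338. That split put placebo replicate 1, Lira replicate 1 and Lira replicate 3 on one side, a structure of the arrays that does not follow treatment. These arrays also had the lowest mean log2 signals of the spike-in control probe sets, 11.901 to 12.023, against 12.093 to 12.318 on the others. Whether the arrays or the mice underlie this structure was not tested. For the 7 gene lists, 2 of 10 splits gave as many, and the highest other gave 9.

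Heat shock, immediate early and glucocorticoid target lists were each shifted lower with Lira at the preset correlation in camera, and none passed with an estimated correlation (adjusted p = 0.70 for each). A difference in RNA quality between the groups is argued against, since the log2 ratio of the 3-prime to the 5-prime actin control differed by 0.037 ± 0.046 (SE), within 0.3 of 0. A difference in overall signal scale was not decided: 3 of the 3 lists passed after quantile normalisation, but this hardly moved the groups against each other (median log2 difference of all genes 0.0086 before and 0.0037 after). A different time of day at dissection stays open: clock genes that peak with Dbp minus those that peak with Arntl differed by -0.324 ± 0.127, neither beyond 0.2 nor within 0.5 in size by 2 SE, and no dissection times are used here. A lower stress or hormone response under Lira is a candidate explanation that the design names only through the treatment, and it was not tested.

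Antigen presentation, macrophage marker and interferon response lists were shifted higher with Lira at the preset correlation in camera, with the groups overlapping on the arrays, and none passed with an estimated correlation (adjusted p = 0.70 for each). A single Lira array as the source of all 3 is argued against only weakly. At the preset correlation at least 1 list passed whichever Lira array was left out (2, 1 and 3 lists without replicates 1, 2 and 3). That setting also passed up to 9 lists in other splits of the arrays. For each list alone a single array stays open: antigen presentation (0.18) and interferon response (0.35) lost the call without Lira replicate 2, and macrophage markers (0.16) without Lira replicate 1. More leukocytes in the Lira samples may account for part of the pattern: the mean of 13 general leukocyte genes, none of them on a fixed list, was 0.199 ± 0.068 higher. Higher expression per cell, and leukocytes of blood left in the tissue, stay open and were not tested.

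Acta1 was lower with Lira, and Nppa and Myh7 had lower values that passed only adjusted over the list alone. Enough skeletal muscle in the placebo samples to give the fall of Acta1 is argued against, since it would bring other abundant transcripts. Placebo mean signal plus 2 SD was at most 102 in all 10 fast skeletal muscle genes, below 139, which is 10% of the fall of Acta1 in signal; probe sets differ in brightness, so this rests on all 10 together. A smaller share stays open: the mean of the 10 genes differed by -0.085 ± 0.073, and the 4 of them above the filter on low values had lower values, from -0.48 for Myh2 to -0.07 for Tnni2, none of which passed. Atrial tissue in the placebo samples cannot be told apart for Nppa: the mean of Myl7, Myl4, Sln and Bmp10, with placebo means from 8.97 for Myl7 to 92.9 for Myl4, differed by -0.218 ± 0.327. A lower load on the heart was not tested.

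As a hypothesis, lower values of Ddit4, Irs2, Depp1 and Gadd45a, each known as a FOXO target and grouped after their values were seen, may reflect lower FOXO activity. Of these only Ddit4 passed over all genes. Depp1, at 1700 ± 192 and 1205 ± 112, Irs2, and Gadd45a, at 260 ± 19.4 and 160 ± 57.3, did not (adjusted p of 0.28, 0.51 and 0.57, limma). By the bound written for the test, a fall shared by other FOXO targets is argued against. The mean of 19 other FOXO targets, among them Fbxo32 and Trim63, differed by 0.044 ± 0.045 (SE) with Lira, above the bound of -0.2 set for it. Of these targets 11 were higher and 8 lower, from -0.37 for Sesn1 to 0.46 for Gabarapl1. Only the further condition, that a mean over genes going both ways does not decide, left the test open. For Ddit4, Irs2, Depp1 and Gadd45a themselves the cause was not tested.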
